A study of Macaca mulatta with 11 samples.

How the data were processed

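RNA of rhesus monkey cumulus cells was measured on 11 Affymetrix Rhesus Macaque arrays, 1 sample per array. Per the labels, RNA was extracted with a PicoPure kit and 50 ng of total RNA per sample was amplified by repeated reverse and in vitro transcription and labelled with biotin. The samples form 3 groups taken from their titles: 4 pre-maturation samples (PM), 3 samples after in vitro maturation (IVM) and 4 after in vivo maturation (VVM). Nothing in the labels says that the samples of a group came from separate animals, so the p-values measure only the spread between these samples. Their number limits the precision.

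The deposited values are intensity, made by the authors with RMA, which corrects background, brings all arrays to 1 distribution and summarises the probes of a probe set. The submitters' processing notes name Affymetrix Expression Console and RMA, with no versions or settings. All values lay above 0 and the array medians lay between 40.6 and 46.1, so the table is on a linear scale, and log2 was taken before any other step. No pseudocount was added. The table held 52865 probe sets, and the 99 control probe sets of the array maker were left out of the tests, which leaves 52766. Of these, 24956 carried 1 gene symbol, 361 carried several and 27449 carried none in the annotation used here. The symbols came from the array annotation, and 24629 of its 25330 rows matched a gene of the current RefSeq annotation by gene identifier. A gene was represented by the probe set with 1 symbol and the highest mean log2 value over all 11 arrays, which gave 14132 genes, 6375 of them with more than 1 probe set. No genome positions were used. Signal over background was not used here, and a fold against a group below the array medians is at best a lower bound.

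Group differences came from limma 3.58.1 in R 4.3.3, in 1 linear model with the 3 group means and empirical Bayes moderation, with 8 residual and 3.30 prior degrees of freedom. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 52766 probe sets, separately for each of the 3 comparisons. A gene is called when its adjusted p is under 0.05. Each log2 difference is given with the standard error of the moderated fit. The test was tested on simulated data: with 100 probe sets changed by 1 on the log2 scale, 54%, 56% and 55% were recovered for IVM against VVM, IVM against PM and VVM against PM, and with a change of 2 on that scale 85%, 92% and 93% were. These runs made 9, 9 and 5 false calls over 52766 probe sets, among 148, 157 and 153 calls. They changed far fewer probe sets than were called in the data and used independent noise. Recovery and false calls in the data can therefore differ from these values.

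Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 31 lists in each comparison. The lists cover 24 processes and 7 other cell types and name 749 genes, of which 528 were measured. A separate set of 26 genes of cumulus and granulosa biology was fixed for naming, of which 17 carried a symbol on this array. Those without a symbol, among them PTGS2, EREG, LHCGR, FSHR, CYP11A1, GJA1 and VEGFA, are not analysed here. The genes named in each comparison follow 1 rule: the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap array by array and whose symbol is not a placeholder, every measured gene of the fixed set, and up to 4 members with the largest absolute difference in each list. Genes named outside the rule are said to be so. The groups, the model, the lists, the rule for named genes and all but 3 of the alternative settings were chosen before the data were examined.

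Changes from PM in IVM and in VVM share the PM arrays, which alone makes them correlated. Their overlap was therefore set against the product of the list sizes, and against the 6 ways of splitting the 4 shared arrays so that each comparison has its own, and the correlation of the changes also against 20 simulations of unchanged groups that keep the shared arrays. The replicate numbers of the titles were checked for pairing: residuals of arrays with the same number correlated between -0.107 and 0.101, so the numbers were not used in the model. Alternatives changed the normalization, the filter on dim or cross-hybridizing probe sets, the threshold, the representative probe set, the prior, array weights, the set test, the arrays used, and covariates for RNA quality and replicate number. After the data were seen, 3 were added: the level of the bacterial hybridization control probe sets as a covariate, PM 1, VVM 2 and VVM 3 left out together, and, for the counts of genes and the inflammatory list, the mean level of LYZ, TYROBP, CD14 and PTPRC as a covariate.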

Results

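Expression was measured in cumulus cells, the somatic cells that surround the oocyte in the cumulus-oocyte complex. The 4 PM samples came from immature complexes after follicle-stimulating hormone (FSH) alone. The 3 IVM samples came from complexes matured in culture after FSH. The 4 VVM samples came from complexes matured in the animal after FSH and human chorionic gonadotropin. The array medians ranged from 5.34 to 5.53 on the log2 scale. Pearson correlations across probe sets, which are not independent replicates, ranged from 0.980 to 0.987 within PM, from 0.974 to 0.977 within IVM and from 0.977 to 0.984 within VVM. Between groups they ranged from 0.940 to 0.962 for IVM and VVM, from 0.909 to 0.952 for PM and IVM, and from 0.924 to 0.952 for PM and VVM. All 11 arrays were closer to their own group than to either other group.

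**Figure D1:**
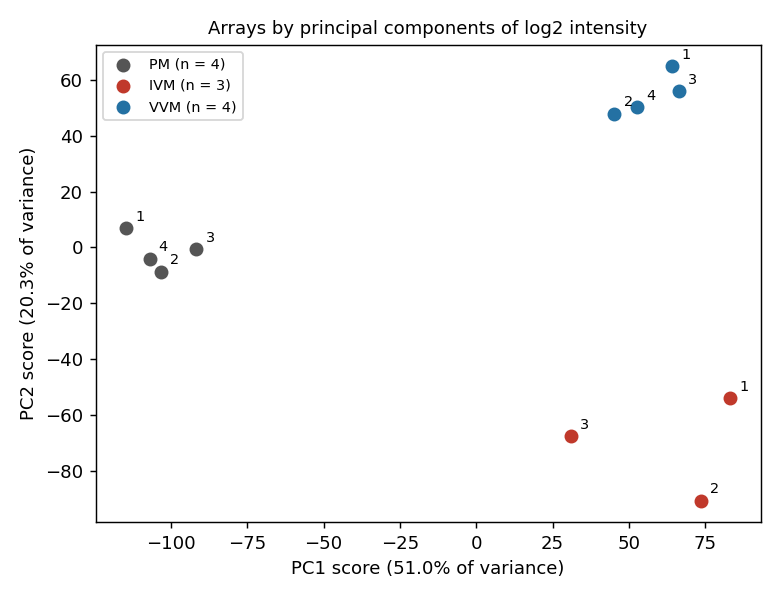
Scores of the 11 arrays on the first principal components of log2 intensity (horizontal axis 51.0% and vertical axis 20.3% of the variance), with each point 1 array numbered by replicate. PM lies apart from IVM and VVM on the horizontal axis, and IVM and VVM lie on opposite sides of the vertical axis.

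The comparison of IVM with VVM asks which cumulus transcripts differ between culture and in vivo maturation, which the series design names as potential markers of oocyte quality. AREG, an EGF-like ligand that relays the luteinizing hormone signal, was at 6.63 ± 1.31 (SD, n = 3) on the log2 scale in IVM and at 11.37 ± 0.84 (SD, n = 4) in VVM, a fold of 26.6 (log2 difference -4.73 ± 0.58 SE, adjusted p = 0.00076). PTX3, a component of the expanded cumulus matrix, was 29.9-fold lower in IVM (-4.90 ± 0.81 SE, adjusted p = 0.0034). In the other direction, GJA5, a gap junction connexin, was 24.8-fold higher in IVM (4.63 ± 0.62 SE, adjusted p = 0.00117). SMAD7, an inhibitor of TGF-beta signalling, was at 9.37 ± 0.19 (SD, n = 3) in IVM and 5.51 ± 0.20 (SD, n = 4) in VVM, a fold of 14.5. In total 1280 genes were higher and 1078 were lower in IVM, of 14132. With each array centred on its median these were 1072 and 1117, and the share of calls that were rises went from 54.3% to 49.0%. With the mean level of the leukocyte genes LYZ, TYROBP, CD14 and PTPRC as a covariate, chosen after the data were seen, 1215 genes were called, and 1058 of the 2358 calls were kept.

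Among the 10 largest rises in IVM over VVM, BMPER, a secreted BMP-binding protein, rose by 4.32 ± 0.49 on the log2 scale (SE, n = 3 and 4 here and below). ASNS, which makes asparagine, rose by 4.09 ± 0.60 and SLC7A11, a cystine transporter, by 3.95 ± 0.58 (1 of 2 probe sets). CYP3A5 rose by 3.82 ± 0.38, the netrin receptor gene UNC5B by 3.79 ± 0.43, PCK1, an enzyme of gluconeogenesis, by 3.42 ± 0.50 and SPON2 by 3.11 ± 0.43. VAT1L rose by 3.31 ± 0.91, and its call was lost without PM 2, IVM 1, IVM 2, IVM 3, VVM 2, VVM 3 or VVM 4, with differences from 2.87 to 3.73 and adjusted p up to 0.132. Among the 10 largest falls, GPRC5B fell by 4.72 ± 0.26, KIT, the receptor of KIT ligand, by 4.51 ± 0.60, TMPRSS7 by 4.46 ± 0.47 and VCAM1, an adhesion molecule, by 4.21 ± 0.44. EGR2, an immediate early transcription factor, fell by 5.38 ± 0.57, AADAC by 5.21 ± 0.85 and PYROXD1 by 4.68 ± 0.36, each with only 1 of its 2, 2 and 3 probe sets called in that direction. The largest of the named falls, 8.55 ± 0.47, was in the probe sets annotated as USP14, and all 5 of them fell. That name is doubtful, since 1 of the 5 comes from the same design cluster as the probe set of HBB, a globin gene.

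**Figure D2:**
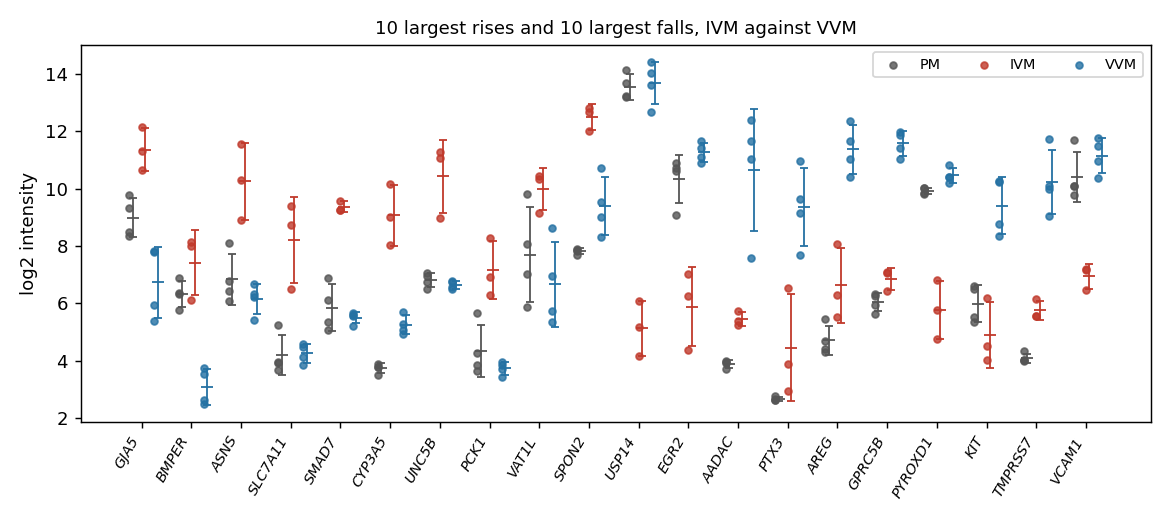
Log2 intensity (vertical axis) of the 10 genes with the largest rise and the 10 with the largest fall in IVM against VVM (horizontal axis), with each dot 1 array of PM (n = 4), IVM (n = 3) or VVM (n = 4) and bars for the mean ± SD. GJA5 averages 11.37 in IVM and 6.73 in VVM, and AREG averages 6.63 and 11.37.

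Of the 17 fixed genes, 6 passed the test between IVM and VVM. Besides AREG and PTX3, these were genes of steroid hormone synthesis and response: HSD3B2 rose by 2.19 ± 0.40 in IVM, CYP19A1, which makes oestrogen, by 1.91 ± 0.41, and PGR, the progesterone receptor, by 1.42 ± 0.26. INHBA, an activin subunit, rose by 1.30 ± 0.33, and this call was lost without IVM 1, IVM 3, VVM 1, VVM 3 or VVM 4, with differences from 1.03 to 1.35 and adjusted p up to 0.0789. The differences that did not pass were -1.29 for ADAMTS1, 1.61 for AMH, -0.91 for EGFR, -0.41 for FST, 0.48 for GREM1, 0.33 for HAS2, 0.03 for LDHA, 0.40 for PFKP, -0.98 for STAR, -0.68 for TNFAIP6 and 0.41 for VCAN. Some of these passed when 1 array was left out: AMH without IVM 1 (2.18), EGFR without PM 4 (-0.91) or VVM 1 (-1.10), TNFAIP6 without VVM 3 (-1.21) and VCAN without VVM 4 (0.51). The sign of the HAS2 difference turned without IVM 1 (-0.09), and that of LDHA without IVM 1 (-0.08), VVM 2 (-0.03) or VVM 3 (-0.06).

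Immediate early genes, which are induced within minutes of a stimulus, were lower in IVM than in VVM: 7 of 13 measured members fell and none rose (0 and 11 adjusted over the list alone), with log2 differences of -3.01 ± 0.19 for KLF6, -3.45 ± 0.70 for KLF4 and -2.14 ± 0.24 for NR4A1 (camera adjusted p = 1.19e-08, and adjusted p = 0.619 with an estimated correlation). Of the list of EGF receptor signalling and its feedback genes, 4 of 15 fell, among them AREG, the ligand BTC (-2.55 ± 0.38) and the feedback inhibitor SPRY1 (-2.13 ± 0.23), and ERBB3 rose by 2.33 ± 0.52 (1 and 6 adjusted over the list alone). That list's adjusted p was 0.0234, and adjusted p = 0.650 with an estimated correlation. Hypoxia response genes fell in 6 of 14 cases (1 higher and 6 lower adjusted over the list alone), such as ERO1A (-1.89 ± 0.36) and MXI1 (-1.81 ± 0.32), with adjusted p = 0.0338, and adjusted p = 0.677 with an estimated correlation. Mitochondrial respiratory chain genes were higher, with 6 of 31 up and ATP5F1B down (14 and 2 adjusted over the list alone), such as ATP5MC1 (1.02 ± 0.17) and ATP5PO (0.92 ± 0.15), with adjusted p = 0.0338, and adjusted p = 0.650 with an estimated correlation. ATP5F1B, with a difference of -1.03 ± 0.22, lost its call without IVM 2 (-0.80).

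Cytokine genes were part of the same comparison. IL1R2, a decoy receptor of interleukin 1, fell by 1.74 ± 0.32, and IL1RN by 2.91 ± 0.81, the 2 called of 23 measured members of the inflammatory list (0 higher and 2 lower adjusted over the list alone). The list's adjusted p was 0.0338, and adjusted p = 0.650 with an estimated correlation. Leukocyte markers moved with it: 3 of 18 were lower in IVM, namely LYZ (-3.20 ± 0.90), TYROBP (-2.69 ± 0.68) and MAMU-DRA (-2.75 ± 0.73), with none higher (0 and 3 adjusted over the list alone), adjusted p = 0.0234, and adjusted p = 0.677 with an estimated correlation. Of all genes, 16.7% were called in IVM against VVM, so the 2 of 23 and the 3 of 18 are not high shares. In VVM 2 and VVM 3, LYZ stood at 7.62 and 9.51, against 5.10 in VVM 1 and 4.79 in VVM 4. The calls of IL1RN and LYZ were lost without any 1 of 9 and 8 arrays: IL1RN without any but VVM 1 and VVM 4, with adjusted p up to 0.123, and LYZ without any but VVM 1, VVM 3 and VVM 4, up to 0.127. With PM 1, VVM 2 and VVM 3 left out together, the shift of the inflammatory list went from -0.59 to -0.28 (adjusted p = 0.519) and that of the leukocyte list from -0.84 to -0.13 (adjusted p = 0.516), and both calls were lost. TYROBP and MAMU-DRA were lost without IVM 1, IVM 2, IVM 3 or VVM 2, with adjusted p up to 0.0769 and 0.0927.

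Other groups showed members called mostly in 1 direction without a call of the list. Of 19 genes of granulosa identity and FSH response, 7 were higher in IVM and none lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.188), CYP19A1 among them. Of 14 steroid synthesis genes 6 rose and HSD11B1, which regenerates active glucocorticoid, fell by 3.90 ± 0.58 (7 and 2 adjusted over the list alone, adjusted p = 0.251). Of 21 expansion and ovulation genes 4 fell and PGR rose (3 and 4 adjusted over the list alone, adjusted p = 0.202). Of 30 genes of TGF-beta and BMP signalling, 6 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.764), including SMAD6, which rose by 2.84 ± 0.54. In the insulin and IGF list 4 of 17 fell (0 and 5 adjusted over the list alone, adjusted p = 0.196), with IGFBP1 at -4.13 ± 0.71 and IRS2 at -1.76 ± 0.27. That list's median difference was 0.08 while its mean was -0.54 and its test pointed lower.

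The counts rested in part on single arrays. Without IVM 2, 803 genes were higher and 620 lower in IVM than in VVM, and the lists called numbered 3 in place of 6, as they did without VVM 2; they numbered 2 without IVM 3 and 1 without VVM 3. The EGF receptor list was lost without IVM 2 (adjusted p = 0.0569), IVM 3 (0.0530) or VVM 3 (0.0773), the hypoxia list without IVM 2 (0.0589), IVM 3 (0.0621), VVM 1 (0.0747), VVM 3 (0.0636) or VVM 4 (0.136), and the mitochondrial list without IVM 3 (0.243), VVM 2 (0.0743) or VVM 3 (0.0793). The inflammatory list was lost without IVM 2 (0.0569), IVM 3 (0.115), VVM 2 (0.153) or VVM 3 (0.101), and the leukocyte list without IVM 3 (0.0621), VVM 2 (0.153) or VVM 3 (0.0636), while the immediate early list was called in each of these fits. The 5 lists other than the immediate early genes were also lost when probe sets dimmer than the median were left out (adjusted p from 0.0665 to 0.191), while the shifts went from -0.78 to -0.81 for the EGF receptor list, from 0.26 to 0.29 for the mitochondrial list, from -0.59 to -0.73 for the inflammatory list, from -0.57 to -0.50 for the hypoxia list and from -0.84 to -0.67 for the leukocyte list. With a mean log2 of at least 6, the inflammatory and leukocyte lists (0.288 for both) and the EGF receptor and mitochondrial lists (0.104 for both) were lost. Without probe sets that can cross-hybridize, the inflammatory (0.0777), leukocyte (0.0925) and mitochondrial (0.196) lists were lost. Fry lost the inflammatory (0.109) and leukocyte (0.223) lists, and centring lost the inflammatory list (0.0540). The hypoxia list was lost in 17 of 26 alternatives. Beyond those given, these were the level of the hybridization controls as a covariate (shift -0.23, adjusted p = 0.230), centring (0.0587), quantile normalization again (0.0569), cyclic loess (0.105), array weights (0.0712), the replicate block (0.0646), the 3 prime to 5 prime covariate (0.0522), the probe sets with a mean log2 of at least 6 (0.288), those that cannot cross-hybridize (0.0832) and fry (0.0884). It was called with PM 1, VVM 2 and VVM 3 left out (shift -0.97, adjusted p = 0.00241), a fit that lost the EGF receptor list (shift -0.65) and the mitochondrial list (0.23), both at an adjusted p of 0.140. With the level of the hybridization control probe sets as a covariate, 197 genes were higher and 132 lower. Of all 52766 probe sets, 5989 differed between IVM and VVM, and 2262 of these had no single gene name here. At the threshold of an adjusted p under 0.05 and at least 2-fold, 442 genes were higher and 686 lower. Without IVM 2 the probe sets numbered 3445.

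IVM was compared with PM to describe the transition in culture. EFEMP1, an extracellular matrix glycoprotein, went from 4.67 ± 0.82 (SD, n = 4) in PM to 11.15 ± 0.85 (SD, n = 3) in IVM, a fold of 89.3 (log2 difference 6.48 ± 0.61 SE, adjusted p = 3.2e-05). Its mean in PM lay below the array medians, so this fold is at best a lower bound. STAR, which delivers cholesterol to the mitochondrion for steroid synthesis, rose 52.6-fold (5.72 ± 0.60 SE) and IGFBP3, a binding protein of insulin-like growth factors, 58.2-fold (5.86 ± 0.32 SE). Genes of cell division fell, such as the proliferation marker MKI67, by 3.91 ± 0.40 on the log2 scale. In total 3539 genes were higher and 2953 lower in IVM than in PM. With each array centred on its median these were 2078 and 3406, and the share of calls that were rises went from 54.5% to 37.9%. The median difference over all genes was 0.12, while the upper quartiles of the IVM arrays (7.08 to 7.14) lay below those of the PM arrays (7.22 to 7.31).

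Of the other large rises from PM to IVM, MMP10, a matrix metalloproteinase, rose by 5.98 ± 0.73 (SE, n = 3 and 4), SRGN, a proteoglycan core protein, by 5.85 ± 0.28, RGS2, a regulator of G protein signalling, by 5.65 ± 1.01 and PDE5A, a cyclic GMP phosphodiesterase, by 5.48 ± 0.31. CYP3A5 rose by 5.33 ± 0.38, DHRS9 by 5.00 ± 0.63 and MOCOS by 4.95 ± 0.54. Among the falls, CKAP2 fell by 5.38 ± 0.49, HMGB2 by 4.64 ± 0.49, the cell cycle transcription factors FOXM1 by 4.45 ± 0.43 and E2F7 by 4.41 ± 0.40, GABRP by 4.55 ± 0.46, MAP6D1 by 4.77 ± 0.88 and USP21 by 4.68 ± 0.57. EGR2 fell by 4.45 ± 0.57 and HSF4 by 4.84 ± 0.57. For CKAP2, HMGB2, E2F7, EGR2 and HSF4 1 of 2 probe sets was called. The probe sets annotated as USP14 fell by 8.42 ± 0.47, with the doubt about their name given for the comparison with VVM.

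Of the fixed genes, TNFAIP6, which links the hyaluronan matrix, rose in IVM by 4.20 ± 0.50, the protease gene ADAMTS1 by 2.92 ± 0.58, the hyaluronan synthase HAS2 by 2.61 ± 0.58 and VCAN by 1.05 ± 0.13. HSD3B2 rose by 2.07 ± 0.40 and PGR by 1.72 ± 0.26. AREG rose by 1.92 ± 0.58, a call lost without PM 1 (1.81), PM 3 (1.78) or IVM 1 (1.19). EGFR fell by 1.52 ± 0.30, PFKP by 1.32 ± 0.25, GREM1 by 1.14 ± 0.19, FST by 1.04 ± 0.24 and AMH by 1.87 ± 0.53, the last lost without IVM 1 (-1.30). The differences that did not pass were 1.79 for PTX3, which passed without IVM 3 (2.55) and was 0.74 without IVM 1, -0.05 for CYP19A1, whose sign turned without PM 2 (0.25) or PM 3 (0.12), 0.48 for INHBA and -0.24 for LDHA.

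**Figure D3:**
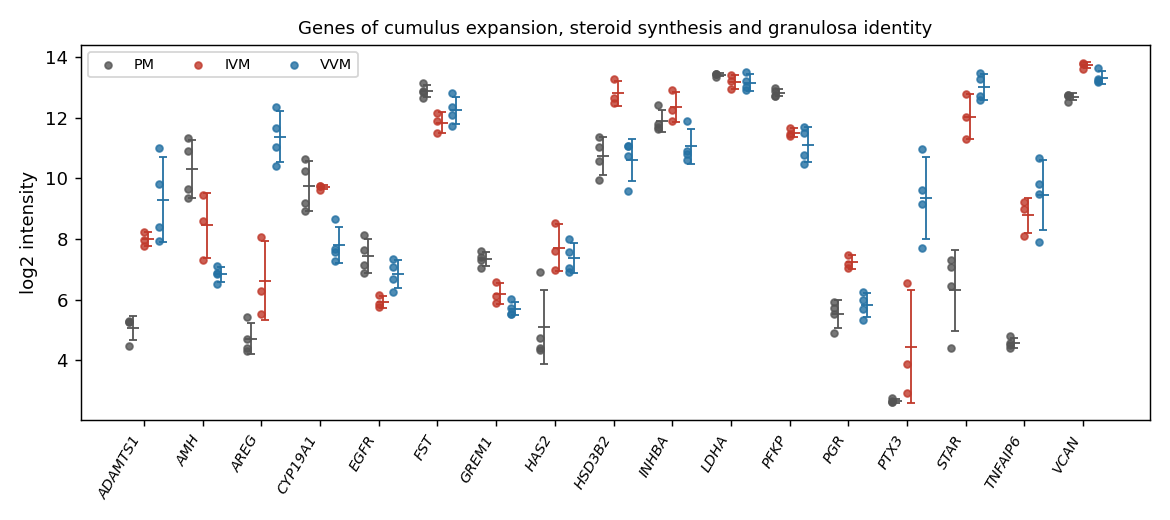
Log2 intensity (vertical axis) of the 17 measured genes fixed for naming (horizontal axis), with each dot 1 array of PM (n = 4), IVM (n = 3) or VVM (n = 4) and bars for the mean ± SD. STAR averages 6.31 in PM, 12.03 in IVM and 13.01 in VVM, and CYP19A1 averages 9.76, 9.71 and 7.80.

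Cell cycle genes fell together: 23 of 26 were lower in IVM than in PM and 2 were higher (2 and 24 adjusted over the list alone), with differences of -3.76 ± 0.51 for MAD2L1, -3.68 ± 0.41 for CCNB1 and -3.59 ± 0.24 for CCNE2 (adjusted p = 3.04e-09, and adjusted p = 0.499 with an estimated correlation). Of 13 immediate early genes 9 fell and 1 rose (1 and 9 adjusted over the list alone), such as KLF6 (-2.78 ± 0.19) and NR4A1 (-2.73 ± 0.24), with adjusted p = 0.000735, and adjusted p = 0.499 with an estimated correlation. Of 19 glycolysis and lactate transport genes 9 fell and 2 rose (2 and 10 adjusted over the list alone), such as the monocarboxylate carrier SLC16A1 (-4.24 ± 0.37), the glucose transporter SLC2A1 (-2.20 ± 0.38) and PFKL (-2.05 ± 0.21), with adjusted p = 0.00147, and adjusted p = 0.499 with an estimated correlation. These 3 lists were called in each fit that left out 1 array, and glycolysis was lost with the level of the hybridization controls as a covariate (adjusted p = 0.328).

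Lists without a call also held members that passed. Of 39 extracellular matrix genes 16 rose and 9 fell from PM to IVM (17 and 11 adjusted over the list alone, adjusted p = 0.359), with TIMP1, an inhibitor of metalloproteinases, up by 3.25 ± 0.16 and CCN2 at a difference of -3.21 ± 0.54. Of 21 expansion and ovulation genes 10 rose and 4 fell (10 and 4 adjusted over the list alone, adjusted p = 0.347). Of 14 amino acid transporters 7 rose and none fell (7 and 0 adjusted over the list alone, adjusted p = 0.230), such as SLC7A11 (4.01 ± 0.58), and of 19 oxidative stress genes 11 rose and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 0.230). SMAD7 and SMAD6 rose by 3.51 ± 0.34 and 3.49 ± 0.54 while SMAD4 fell by 2.43 ± 0.31, in a TGF-beta list with 4 higher and 10 lower of 30 (4 and 11 adjusted over the list alone, adjusted p = 0.230).

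The hybridization controls, bacterial transcripts added to each sample after labelling, averaged 10.09 ± 0.21 (SD, n = 4) in PM, 11.92 ± 0.40 (SD, n = 3) in IVM and 11.04 ± 0.43 (SD, n = 4) in VVM. Every IVM array lay above every PM array in this level, and with it as a covariate, an alternative added after the data were seen, 2 genes passed in limma, both lower in IVM than in PM. At an unadjusted p under 0.05 the numbers were 1171 higher and 993 lower. The standard error of a called gene's difference had a median of 0.18 without and 0.44 with the covariate. With the 3 prime to 5 prime difference of control transcripts as a covariate, taken as a measure of RNA integrity, 1085 genes were higher and 1357 lower. It averaged 3.34 in PM and 3.91 in IVM. The PM arrays (3.20 to 3.45) and the IVM arrays (3.67 to 4.36) did not overlap in it. That fit therefore rests on the spread within groups. The actin control alone also separated the groups, at 3.66 to 3.96 in PM and 4.57 to 5.14 in IVM. The GAPDH control did not, at 2.705 to 2.998 in PM and 2.728 to 3.585 in IVM. Whether the difference between groups reflects RNA integrity was not tested. Of all 52766 probe sets 21448 differed between IVM and PM, 10614 of them without a single gene name here, and 8 did with the hybridization level as a covariate.

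**Figure D4:**
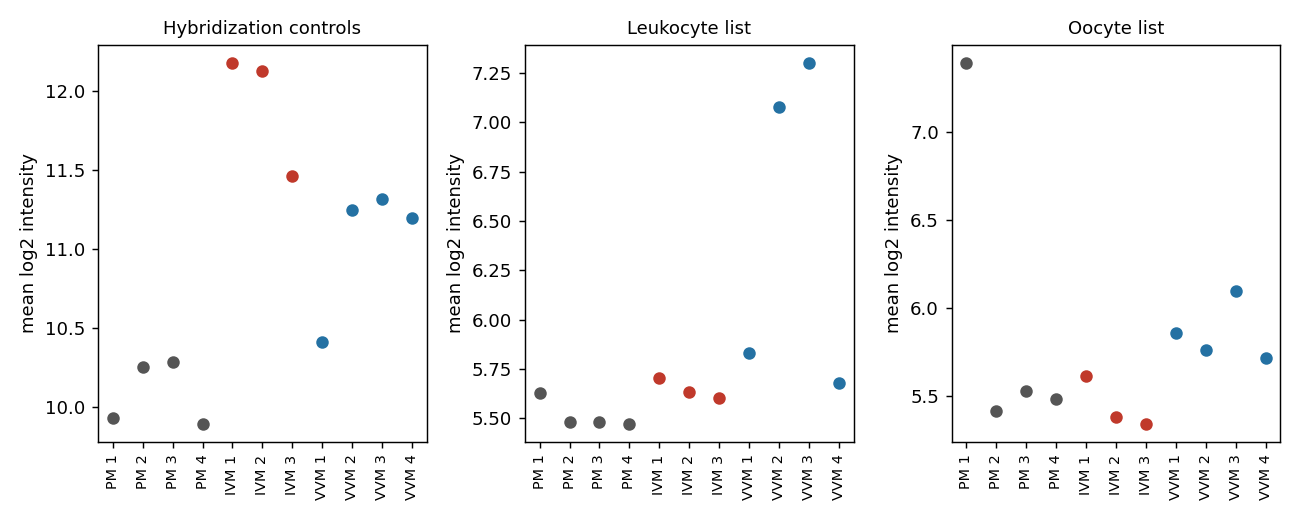
Mean log2 intensity (vertical axes) of the hybridization controls, the leukocyte list and the oocyte list in each of the 11 arrays (horizontal axes), coloured by group as PM grey, IVM red and VVM blue. The oocyte list is at 7.40 in PM 1 against 5.41 to 5.53 in the other PM arrays, and the leukocyte list is at 7.08 and 7.30 in VVM 2 and VVM 3.

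VVM was compared with PM to describe the transition in the animal. HSD11B1 went from 5.25 ± 0.38 (SD, n = 4) in PM to 13.02 ± 0.50 (SD, n = 4) in VVM, a fold of 218 (log2 difference 7.77 ± 0.54 SE, adjusted p = 7.8e-06). STAR rose 104-fold (6.70 ± 0.56 SE), PTX3 103-fold (6.69 ± 0.75 SE) and AREG 100-fold (6.65 ± 0.54 SE). The PM means of HSD11B1, PTX3 and AREG lay below the array medians, so these 3 folds are at best lower bounds. AMH, a hormone of small-follicle granulosa cells, fell by 3.48 ± 0.49 on the log2 scale, and CYP19A1 by 1.96 ± 0.38. In total 2548 genes were higher and 3074 lower in VVM than in PM. With each array centred on its median these were 1708 and 3530, and the share of calls that were rises went from 45.3% to 32.6%. The 3 prime to 5 prime difference of the actin control was 3.66 to 3.96 in PM and 4.52 to 4.95 in VVM. That of the GAPDH control averaged 2.83 in PM and 2.68 in VVM, with overlapping arrays. With the mean difference of the actin and GAPDH controls as a covariate 1325 genes were higher and 1973 lower. With the mean level of LYZ, TYROBP, CD14 and PTPRC as a covariate 2461 genes were called, and 2344 of the 5622 calls were kept.

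The other large rises from PM to VVM were TM4SF1 (7.14 ± 0.58 SE, n = 4 and 4), AADAC (6.78 ± 0.78, 1 of 2 probe sets), the transcription factor CEBPA (6.40 ± 0.48), MOCOS (6.40 ± 0.50), SRGN (6.21 ± 0.26) and TMPRSS7 (6.13 ± 0.43). The falls included GABRP (-4.80 ± 0.43), E2F7 (-4.50 ± 0.37, 1 of 2 probe sets), the actin-binding ABLIM1 (-4.48 ± 0.24), MEX3B (-4.38 ± 0.35), GNB5 (-4.35 ± 0.38), CORO2A (-4.31 ± 0.27), the glycine cleavage enzyme GLDC (-4.16 ± 0.25), USP21 (-4.04 ± 0.53) and EFNB1 (-4.02 ± 0.71). A probe set annotated as SRY fell by 4.94 ± 0.24, but the other with that name differed by 0.23 (adjusted p = 0.222), so the name is doubtful. Of the fixed genes, TNFAIP6 rose by 4.88 ± 0.47, ADAMTS1 by 4.22 ± 0.54, HAS2 by 2.29 ± 0.54 and VCAN by 0.64 ± 0.12. PFKP fell by 1.72 ± 0.23 and GREM1 by 1.63 ± 0.18. FST fell by 0.64 ± 0.22, a call lost without any PM array, IVM 1, VVM 1, VVM 2 or VVM 3, with differences from -0.71 to -0.47 and adjusted p up to 0.125. The differences that did not pass were -0.61 for EGFR, -0.13 for HSD3B2, whose sign turned without PM 4 (0.09) or VVM 1 (0.22), -0.26 for LDHA, 0.29 for PGR and -0.82 for INHBA, which passed without IVM 3 (-0.82) or VVM 2 (-1.11).

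Cell cycle genes fell from PM to VVM as well, 21 of 26 with 1 higher (1 and 22 adjusted over the list alone). The differences were -3.87 ± 0.22 for CCNE2, -3.10 ± 0.46 for MCM2 and -3.06 ± 0.39 for MCM5, while the cell cycle inhibitor CDKN1A rose by 3.05 ± 0.37 (adjusted p = 1.29e-07, and adjusted p = 0.577 with an estimated correlation). Of 19 genes of granulosa identity and FSH response 11 fell and 2 rose (2 and 13 adjusted over the list alone), such as HSD17B1 (-3.32 ± 0.43) and GATA4 (-2.94 ± 0.21), with adjusted p = 0.0197, and adjusted p = 0.577 with an estimated correlation. Of the glycolysis list 10 of 19 fell and 3 rose (3 and 10 adjusted over the list alone), such as SLC16A1 (-3.59 ± 0.35) and PFKL (-1.86 ± 0.19), with adjusted p = 0.0366, and adjusted p = 0.577 with an estimated correlation. TGF-beta and BMP signalling genes fell in 12 of 30 cases and rose in 4 (4 and 16 adjusted over the list alone), such as ACVR1 (-1.87 ± 0.35) and INHBB (-1.79 ± 0.38), with adjusted p = 0.0451, and adjusted p = 0.577 with an estimated correlation. Glycolysis lost its call without VVM 2 (0.0864) or VVM 3 (0.0576), and the TGF-beta list without PM 1 (0.0515), PM 4 (0.0729), VVM 1 (0.0640) or VVM 3 (0.0580), while the cell cycle and granulosa lists were called in each fit that left out 1 array. With each array centred on its median the glycolysis and TGF-beta lists were lost (0.0605 and 0.0834). They were also lost with the level of the hybridization controls as a covariate (0.253 for both) and with PM 1, VVM 2 and VVM 3 left out (0.289 and 0.0900). The glycolysis shift of -0.62 became -0.35 and -0.42 in these 2 fits and stayed at -0.62 with centring. The TGF-beta shift of -0.41 became -0.36 and -0.41, and stayed at -0.41 with centring. In all, glycolysis was lost in 12 and TGF-beta in 13 of 26 alternatives. The others that lost both were cyclic loess (0.0834 and 0.0734), the 3 prime to 5 prime covariate (0.0639 and 0.0717), the probe sets above the median level (0.0579 and 0.170), those with a mean log2 of at least 6 (0.0806 and 0.299) and those that cannot cross-hybridize (0.0728 and 0.0546). Glycolysis was also lost with only the 2 groups compared (0.0532). Apart from the estimated correlation, the granulosa list was lost only with a mean log2 of at least 6 (shift -0.89, adjusted p = 0.0838).

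Inflammatory genes were higher in VVM than in PM: 15 of 23 rose and 1 fell, with the cytokine IL1B higher by 3.89 ± 0.90, IL1RL1 by 3.33 ± 0.43, IL1RN by 3.20 ± 0.75 and OSMR by 2.57 ± 0.26 (18 and 2 adjusted over the list alone, adjusted p = 0.00115, and adjusted p = 0.577 with an estimated correlation). Leukocyte markers rose in the same comparison, 9 of 18 with 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.0221, and adjusted p = 0.614 with an estimated correlation). LYZ rose by 3.19 ± 0.83, TYROBP by 2.89 ± 0.63 and MAMU-DRA by 2.45 ± 0.68, while CSF1R, the macrophage colony-stimulating factor receptor, fell by 2.57 ± 0.48. The leukocyte list lost its call without VVM 2 (adjusted p = 0.0649), and the inflammatory list kept it in each fit that left out 1 array. Levels of these markers differed within VVM: TYROBP stood at 8.14 and 9.90 in VVM 2 and VVM 3, against 6.51 in VVM 1 and 6.25 in VVM 4. The leukocyte list was also lost with the level of the hybridization controls as a covariate (adjusted p = 0.342), with the 3 prime to 5 prime covariate (0.0710), without probe sets that can cross-hybridize (0.0593) and with a mean log2 of at least 6 (0.134).

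**Figure D5:**
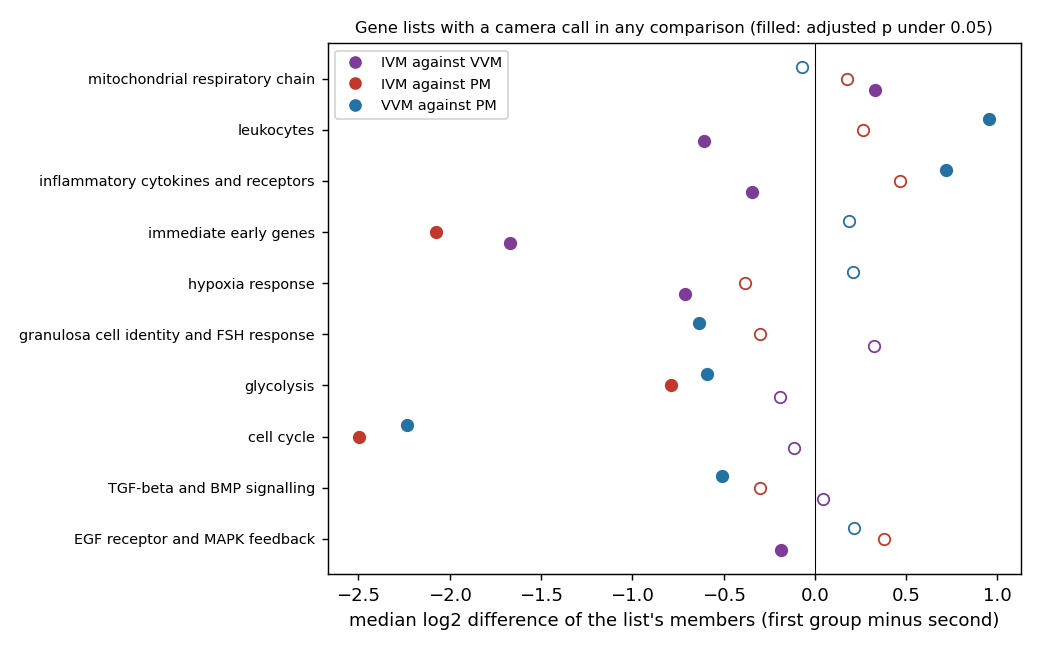
Median log2 difference of the measured members (horizontal axis) of each gene list with a call in any comparison (vertical axis), with a point per comparison filled where the adjusted p at a preset correlation is under 0.05. The cell cycle list has medians of -2.50 in IVM and -2.23 in VVM against PM, and no filled point holds with an estimated correlation.

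Expansion and ovulation genes rose in 12 of 21 cases and fell in 4 from PM to VVM (12 and 4 adjusted over the list alone), with RGS2 up by 5.61 ± 0.94 besides PTX3, AREG and TNFAIP6, and the list's adjusted p was 0.0508. In the insulin and IGF list 7 of 17 rose and 5 fell (9 and 6 adjusted over the list alone, adjusted p = 0.382), with IGFBP3 up by 5.99 ± 0.29, IGFBP1 by 4.38 ± 0.66 and IGF1 by 3.60 ± 0.63. Of 13 immediate early genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.964), with ZFP36, which destabilises cytokine transcripts, up by 4.30 ± 0.45. That list's median was 0.19 and its mean 0.25 while its test pointed lower. The fatty acid list had 5 higher and 5 lower of 21 (5 and 5 adjusted over the list alone, adjusted p = 0.946), with ACSL1 up by 5.25 ± 0.42 and the transporter CD36 by 2.25 ± 0.31. With PM 1, VVM 2 and VVM 3 left out, which held the highest levels of oocyte or leukocyte transcripts, 1153 genes were higher and 1872 lower in VVM than in PM, and with the hybridization level as a covariate 683 and 894 were. Of all 52766 probe sets 16483 differed between VVM and PM, 7213 of them without a single gene name here.

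None of the 15 list calls by camera over the 3 comparisons held with an estimated correlation. At an unadjusted p under 0.05 it gave 1, 0 and 2 lists in IVM against VVM, IVM against PM and VVM against PM. The rotation test fry gave 6, 14 and 16 at an adjusted p under 0.05. Fry asks whether members change at all, while camera asks whether they change more than other genes. With 45.9% and 39.8% of all genes called in IVM and VVM against PM, the fry counts cannot be set beside those of camera. For each of the 15 lists the adjusted p with an estimated correlation was the highest over its alternatives, and the lowest over its alternatives lay between 6.1e-13 and 0.00352.

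The changes from PM in culture and in the animal were compared gene by gene. Of 5622 genes that changed from PM to VVM, 3739 (66.5%) changed the same way in IVM, 1700 up and 2039 down, and 84 went the opposite way. With the 3 prime to 5 prime control difference as a covariate the 3739 became 1465, and with the level of the hybridization controls 2. STAR, SRGN, IGFBP3, TNFAIP6, ADAMTS1 and HAS2 rose in both, and E2F7, GABRP, SLC16A1, CCNE2 and GREM1 fell in both. Lists of these sizes drawn independently would share 638 rises and 642 falls. With the PM arrays split so that each comparison had its own, 776 to 909 genes rose and 1377 to 1482 fell in both. These come from other lists, called with fewer PM arrays, for which no independent value was computed. The log2 changes in IVM and VVM correlated across genes, which are not independent replicates, with r = 0.743. The mean r was 0.464 in the simulations, and r was 0.663 to 0.717 with split PM arrays. The simulated r comes from noise alone and is not a share of the observed r. The covariance of the changes was 0.598, against a mean of 0.0295 in the simulations and 0.559 to 0.586 with split PM arrays.

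Part of the in vivo change was smaller, or of opposite sign, in culture. Of the 5622 genes, 971 (17.3%) differed between IVM and VVM with IVM on the side of PM: 417 that rose in VVM were lower in IVM, and 554 that fell in VVM were higher in IVM. Among them, HSD11B1 stood at 5.25 in PM, 9.12 in IVM and 13.02 in VVM. GPRC5B rose by 5.53 ± 0.24 from PM to VVM and by 0.81 ± 0.26 from PM to IVM, and TMPRSS7 rose by 6.13 ± 0.43 and by 1.67 ± 0.47. AADAC, PTX3, AREG, KIT and IGFBP1 rose from PM to VVM and were lower in IVM than in VVM. BMPER fell by 3.23 ± 0.45 in VVM and did not pass in IVM against PM (1.09 ± 0.49). CYP19A1 fell by 1.96 ± 0.38 in VVM and did not pass in IVM against PM (-0.05 ± 0.41). Independent lists of these sizes would share 194 and 278 genes. VVM against PM and IVM against VVM use the same VVM arrays with opposite sign, so error in these arrays alone adds to the 971. The excess over independent lists is therefore not a measure of biology alone. With the VVM arrays split, 182 to 273 and 210 to 307 did. Those come from other lists, called with fewer VVM arrays per comparison. No independent value was computed for them, so they cannot be set against 194 and 278. Of the 971, 180 had changed in the same direction in IVM from PM. Without IVM 2 the 971 became 637, with the hybridization level as a covariate 82, and with PM 1, VVM 2 and VVM 3 left out 575.

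Of the genes changed from PM, 2669 were called in IVM and not in VVM, and 913 of these also differed between IVM and VVM. Both comparisons use the same 3 IVM arrays, so error in these arrays alone adds to the 913, and no reference value was computed for it. SMAD7 stood at 5.85 in PM, 9.37 in IVM and 5.51 in VVM, and ASNS, SLC7A11, UNC5B, PCK1 and SMAD6 likewise rose in IVM from both. KLF6 stood at 12.34 in PM, 9.56 in IVM and 12.57 in VVM, and NR4A1, KLF4, VCAM1 and PYROXD1 likewise fell in IVM from both. A further 297 genes changed in VVM lay farther from PM in IVM than in VVM, such as SPON2 at 7.82, 12.50 and 9.40 in PM, IVM and VVM. Independent lists of these sizes would share 465. Split arrays gave 76 to 232, from other lists called with fewer VVM arrays, for which no independent value was computed.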

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

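The tests of leukocyte transcripts, of the inflammatory list and of the USP14 probe sets were chosen only after the results were seen, as were the hybridization level as a covariate and the fits without PM 1, VVM 2 and VVM 3. Of 190 sets of 4 arrays examined, 16 had an array far from the other 3, where chance gives about 1 in 20, or 9.5.

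The bacterial hybridization controls, which none of the comparisons use, were higher by 1.84 on the log2 scale (3.57-fold) in IVM than in PM and by 0.95 (1.94-fold) in VVM than in PM. Within VVM, VVM 1 was at 10.41 and the others at 11.20 to 11.32. The groups did not overlap in this level in any of the 3 comparisons, so a fit with it as a covariate rests on the spread within groups. The median difference of the called genes, in the direction called, went from 0.88 to 0.79 for VVM against PM and from 0.97 to 0.90 for IVM against VVM. The median standard error of a gene went from 0.18 to 0.29 and from 0.20 to 0.29, and 1503 of 5622 and 312 of 2358 calls were kept. An effect of the level as steep as the slope within groups would thus leave most of these medians in place. An effect that goes with the group alone cannot be seen by this fit, so the level and the maturation cannot be told apart here. For IVM against PM the median went from 0.83 to 0.59, the median standard error of a gene was 0.44, and 2 of 6492 calls were kept. The level and the maturation in culture cannot be told apart there either, because the groups do not overlap in the level.

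Leukocyte transcripts were high in VVM 2 and VVM 3, where PTPRC, a marker of all leukocytes, stood at 6.89 and 6.58, against 3.98 in VVM 1 and 4.27 in VVM 4, and LYZ at 7.62 and 9.51. Residuals of the 18 measured leukocyte genes had a mean correlation of 0.479, against a median of 0.0153 in 10000 random lists matched on mean level (percentile 100), but the levels in VVM 2 and VVM 3 prompted this test and fix its outcome, so it decides nothing. With the mean level of LYZ, TYROBP, CD14 and PTPRC as a covariate, the median rise of the 15 inflammatory genes that rose from PM to VVM went from 1.26 to 0.41 (quartiles 0.24 and 1.53), with 3 still called. With PM 1, VVM 2 and VVM 3 left out the inflammatory list kept its call in VVM against PM, with a shift of 0.84 in place of 1.18 (adjusted p = 0.00802), and so did the leukocyte list, with 0.34 in place of 1.02 (adjusted p = 0.0306). Leukocytes and a response of the cumulus cells to in vivo maturation cannot be told apart for this list, since the covariate itself differs between PM and VVM and leukocyte transcripts stayed higher in VVM without those arrays.

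The 5 probe sets named USP14 were 177-fold to 375-fold lower in IVM than in VVM, and the gene's name was in doubt. Globin RNA of blood cells is a candidate source: HBB ranked 123 of 14131 genes (0.870% from the top) by the correlation of its residuals with theirs (0.705), and HBA ranked 7 (0.859). Against a single globin source, HBB rose by 1.77 ± 0.32 from PM to VVM, while the USP14 probe set with the highest mean differed by 0.13 ± 0.43. HBB also differed by only -0.995 in IVM against PM and -2.76 in IVM against VVM, where that USP14 probe set differed by -8.42 and -8.55. Globin RNA and another transcript under this name cannot be told apart, because 1 design cluster holds both names and no probe sequences were used.

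In PM 1, 6 values were far from the other PM arrays. The mean of the oocyte list was 7.40 in PM 1 and 5.41 to 5.53 in the others, with ZP3 at 9.57, ZAR1 at 8.47 and NLRP5 at 8.45 in PM 1. The leukocyte list averaged 5.63 against 5.47 to 5.48, RGS2 was at 10.83 against 5.89 to 6.30, ADAMTS1 at 4.48 against 5.25 to 5.29, MMP10 at 3.61 against 3.86 to 3.88, and MEX3B at 9.50 against 8.55 to 8.70. In PM 2, EGR2 was at 9.07 against 10.63 to 10.91, HAS2 at 6.90 against 4.35 to 4.72 and EFNB1 at 10.36 against 11.88 to 11.99. In PM 3, LDHA was at 13.36 against 13.43 to 13.44, ABLIM1 at 11.41 against 12.23 to 12.38, and the inflammatory list averaged 5.94 against 5.80 to 5.82. In PM 4, TMPRSS7 was at 4.33 against 4 to 4.04 and VCAN at 12.51 against 12.72 to 12.76. In VVM 2, CORO2A was at 4.19 against 4.74 to 4.79.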

How the results depend on the processing

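The hybridization level as a covariate and the fits without PM 1, VVM 2 and VVM 3 were chosen only after the data were seen. Of 8977 checks of the named genes and called lists under an alternative, 8102 kept their direction and their side of the threshold, 821 lost a call, 18 gained one and 36 changed sign. With the 3 prime to 5 prime covariate 79 of 134 named genes kept both in IVM against PM, 90 of 102 in IVM against VVM and 96 of 125 in VVM against PM. With the hybridization level as a covariate 2, 39 and 63 did. Signal over background on the arrays limits what can be said of genes of low intensity, and fits without dim probe sets are given below. Counts are given below in the order higher, lower and probe sets where all 3 moved, and the cause was not tested unless fewer probe sets or arrays account for it. Among the splits of the same arrays, only the real one, 1 of 35, gave as many probe sets in each comparison. The counts were 5989 against a highest other of 38 for IVM and VVM and 21448 against 1621 for IVM and PM. For VVM and PM they were 16483 against 0. A share of 1 of 35 is the smallest this test can give, so it argues against chance without excluding it. The other splits mix the groups, which widens the spread within them and lowers their counts.

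Leaving out 1 array, with fewer samples, gave for IVM against VVM 803 to 1228 genes higher, 620 to 1121 lower, 3445 to 6298 probe sets and 1 to 7 lists, for VVM against PM 4 to 9 lists, and 637 to 939 genes with IVM on the side of PM. The lowest of these gene and probe set counts were without IVM 2, and the fewest lists without VVM 3 (IVM against VVM) and VVM 2 (VVM against PM). For IVM against PM the ranges were 2604 to 3568 higher, 2437 to 3016 lower and 16299 to 21994 probe sets, with 3 lists throughout. For VVM against PM they were 1905 to 2641, 2639 to 3151 and 12592 to 17061, and 2928 to 3885 genes changed the same way from PM. Lists in IVM against VVM numbered 3 without IVM 2 or VVM 2 and 2 without IVM 3. In IVM against VVM the sign turned for LDHA without IVM 1 (-0.0845), VVM 2 (-0.0261) and VVM 3 (-0.0581), in a range up to 0.147, and for HAS2 without IVM 1 (-0.0867), in a range up to 0.685. In IVM against PM it turned for CYP19A1 without PM 2 (0.246) and PM 3 (0.116), in a range from -0.321. In VVM against PM it turned for HSD3B2 without PM 4 (0.0882) and VVM 1 (0.219), in a range from -0.385.

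A stricter threshold gives fewer calls by construction. At an adjusted p under 0.01 the counts were 523, 493 and 2366 for IVM against VVM, 1897 higher and 11899 probe sets for IVM against PM, and 1299 higher and 9111 probe sets for VVM against PM, with 2083 genes changed the same way from PM and 366 on the side of PM. With at least 2-fold they were 442, 686 and 2836, then 718, 1810 and 6872, then 798, 1603 and 6111, with 1423 changed the same way and 391 on the side of PM. With shared arrays split, the medians of 6 splits were 2257.5 and 432.5.

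With the 3 prime to 5 prime control difference as a covariate, the counts were 1085, 1357 and 7737 for IVM against PM and 1325, 1973 and 9293 for VVM against PM, with 1465 changed the same way and 618 on the side of PM, and PTX3 in IVM against PM turned to -0.40. With the hybridization level as a covariate they were 197, 132 and 734 for IVM against VVM, 0, 2 and 8 for IVM against PM in limma (1171 and 993 genes at an unadjusted p under 0.05), and 683, 894 and 3976 for VVM against PM, with 2 changed the same way and 82 on the side of PM. Under it these turned in IVM against PM: MX2 (-0.0155), CD68 (-0.0389), ISG15 (-0.55), IL6ST (-0.62), PTX3 (-1.04), TAGLN (-1.30), AREG (-0.0002), CXCR4 (0.18), NLRP7 (0.25), LDHA (0.39), CPT1A (0.76) and UQCRC2 (1.13), and in VVM against PM: BTC (0.012) and LDHA (0.0666). Without PM 1, VVM 2 and VVM 3 the counts were 657 higher, 3243 probe sets and 2 lists for IVM against VVM, and 1153, 1872 and 7735 for VVM against PM, with 2000 changed the same way and 575 on the side of PM. HAS2 (-0.076), PFKP (-0.0828) and LDHA (-0.176) then turned in IVM against VVM.

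With arrays centred on their median, 2078 genes were higher in IVM than in PM, and LDHA turned to -0.015 in IVM against VVM. With quantile normalization again and with cyclic loess, CYP19A1 turned in IVM against PM (0.25 and 0.146) and HSD3B2 in VVM against PM (0.0301 and 0.0487), and with array weights CYP19A1 did (0.0169). Cyclic loess called 6 lists in IVM against PM. Fewer probe sets were tested with those above the median level only, with 13707 called in IVM against PM and 1 list in IVM against VVM. With a mean log2 of at least 6 there were 2215 genes higher and 11390 probe sets in IVM against PM, 10478 probe sets and 2 lists in VVM against PM, and 1 list in IVM against VVM. Without probe sets that can cross-hybridize, 2 lists passed in IVM against VVM and 3 in VVM against PM, and DCN (-1.07 in IVM and -1.33 in VVM against PM), RPL9 (-0.77 in VVM against PM) and NDUFA2 (-0.0777 in IVM against VVM) turned, as another probe set stands for the gene.

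Camera with an estimated correlation called 0 lists in IVM against VVM, 0 in IVM against PM and 0 in VVM against PM (1, 0 and 2 at an unadjusted p under 0.05). Fry called 14 in IVM against PM and 16 in VVM against PM. It does not compare a list with other genes, so a call kept under fry is no check of that comparison. Apart from the estimated correlation, the immediate early lists, the cell cycle lists and the inflammatory list in VVM against PM kept their calls under every alternative in which the list test was run. It was not run with the level of LYZ, TYROBP, CD14 and PTPRC as a covariate. Under that covariate the median rise of the 15 inflammatory genes that rose went from 1.26 to 0.41, with 3 still called.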

Other observations

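None of the tests in this part was chosen after the results were seen. Members of other lists passed without a call of their list, where 39.8% of all genes passed in VVM against PM, 45.9% in IVM against PM and 16.7% in IVM against VVM. HSP90AB1, a cytosolic chaperone, fell by 0.94 ± 0.14 (SE, n = 4 and 4) from PM to VVM in a heat shock list with 1 of 13 higher and 4 lower (1 and 5 adjusted over the list alone, adjusted p = 0.409). MCL1, which protects cells from apoptosis, rose by 1.90 ± 0.16 and BAX, which promotes it, fell by 1.25 ± 0.13, in a list with 4 higher and 3 lower of 18 (4 and 3 adjusted over the list alone, adjusted p = 0.653). From PM to IVM, ANGPTL4 rose by 2.64 ± 0.30 and PDGFB fell by 1.32 ± 0.22, in a list of angiogenic factors with 2 higher and 3 lower of 15 (2 and 3 adjusted over the list alone, adjusted p = 0.662). Between IVM and VVM, FASN, the fatty acid synthase, was higher in IVM by 1.56 ± 0.18 and ACSL1 lower (-2.20 ± 0.45), in a list with 3 higher and 3 lower of 21 (3 and 4 adjusted over the list alone, adjusted p = 0.251).

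In IVM against PM, KRT19, a keratin, rose by 2.44 ± 0.44 among 4 of 11 epithelial markers higher and none lower (4 and 0 adjusted over the list alone, adjusted p = 0.230). In VVM against PM, VWF, a marker of endothelium, rose by 2.32 ± 0.47 while ERG fell by 2.63 ± 0.47, in an endothelial list with 5 higher and 1 lower of 13 (7 and 1 adjusted over the list alone, adjusted p = 0.103). KIT, which the oocyte list holds, rose by 3.42 ± 0.55 from PM to VVM, while that list had 2 of 15 higher and 1 lower (1 and 0 adjusted over the list alone, adjusted p = 0.946), and KIT stood between 8.35 and 10.28 in the VVM arrays against 5.35 to 6.59 in the PM arrays.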
